A study of Homo sapiens with 8 samples.

How the data were processed

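RNA from 8 cultures of MM.1S and NCI-H929 cells, 2 per line and vector, was sequenced after a TruSeq library preparation, per the labels' protocols. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.36.5, STAR 2.6.0b-1, HTSeq 0.9.1 and DESeq2 2.11.40.2 and the genome build GRCh37 (hg19), with no order or settings. The table analysed holds FPKM values as deposited by the authors, for 25906 genes with Entrez IDs, symbols and transcript IDs; the unit was taken from the name of the deposited table and from its values, since the column headers give none. The tool that produced the FPKM and its gene annotation are not given in the sources used here. FPKM divides by transcript length and by library total, so very short transcripts reach high values and genes with near-identical copies can lose or gain reads to them. The share of all FPKM in the top feature, a microRNA gene, was 2.9 to 16.3% per library. Coordinates are not printed, since the reference at hand is of another build.

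Fragments per library were estimated from the steps between low FPKM values of genes with a single transcript longer than 1500 bases, with lengths from GENCODE matched by RefSeq transcript. The estimates were 16000000 to 21000000, and 53.5 to 63.8% of the low values came out whole within 0.1 of a fragment, against 20.0% by chance. They describe relative depth and were not used as counts.

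Samples were grouped by their titles. Replicate numbers within a line name the libraries, and nothing in the labels ties a number to a shared day or culture. Genes with at least 1 FPKM in at least 2 libraries were kept, 12583 in all, and log2(FPKM + 1) was analysed, so fold changes understate those of low genes. The main test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) with Benjamini-Hochberg adjusted p under 0.05. Comparisons within a line, the difference between lines and the baseline used a fit of all 8 libraries with 1 mean per group, and both lines together used a model of line and vector. The 26 gene lists, the tests, the named-gene rule and the alternatives were fixed before the data were examined, except for the naming rule used for the difference between lines. The patterns weighed in the closing section were picked after the leading genes had been seen. Lists were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry beside it, with adjustment over the lists of a comparison. With an estimated correlation camera works with the few residual degrees of freedom of the fit, so it had little power here.

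The named genes are CTBP2, CTBP1, MYC, IRF4, IKZF1, IKZF3, PRDM1 and XBP1, and per comparison up to 10 largest rises and 10 largest falls among called genes. Their CTBP2 libraries had to lie on one side of the empty vector libraries of the same line, with a mean of at least 1 FPKM in the higher group. Clone-style names, CTBP2 and immunoglobulin or T cell receptor segments were left out. For the difference between lines and the baseline the rule takes 5 each way. For the baseline the empty vector libraries of the lines had to lie apart. For the difference between lines no separation of libraries was asked, and any 1 library at 1 FPKM or more was enough. This is looser than the rule fixed beforehand, which asked for libraries apart and a group mean of at least 1 FPKM. Some genes that met the rule are not reported here. Of each list, up to 4 called members by smallest p are named in both lines together, or up to 2 as values. FGFR3, WHSC1, MAF, CCND2, ITGB7 and CCND1 served as the line check.

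The alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, a median-of-ratios rescale, quantile normalization, equal totals after leaving out immunoglobulin genes and CTBP2, no variance trend, a replicate block, leaving out each library, and a minimum log2 fold change of 1. Leaving out both CTBP2 replicate 2 libraries, and exchanging their line labels, were added after seeing the data. The exchange is used in the closing section as a test, for IRF4 in both lines together and for the difference of MYC between lines.

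The code was tested on simulated libraries of 12583 genes with 200 changed genes. With right labels, all 100 genes changed by 1 on the log2 scale and all 100 changed by 2 were recovered in both lines together, with 10 false calls. With the CTBP2 replicate 2 libraries exchanged between lines, 27% and 73% were recovered, with 0 false calls, and within MM.1S 0% and 31%. A list shifted by 0.5 was called by camera and 0 of the other lists were. The simulated genes varied independently, so this cannot show how often camera calls lists of correlated genes falsely. Estimated correlations of the real lists in both lines together reached 0.862. Length and GC content came from the longest GENCODE transcript of each gene, matched by current or older symbol.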

Results

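Messenger RNA was measured by sequencing in MM.1S and NCI-H929, established human lines of the plasma cell cancer multiple myeloma, 72 hours after lentiviral transduction with an empty vector or a vector carrying CTBP2, a transcriptional corepressor that binds DNA-bound repressors. Each line and vector had 2 libraries described as biological duplicates, giving 4 groups and 8 libraries. The values were FPKM for 25906 genes. Depth estimated from the steps between low values lay between 16000000 and 21000000 fragments per library. The comparisons ask which transcripts change with CTBP2, and the series title puts MYC and IRF4 at the centre of that question.

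CTBP2 (Entrez 1488) followed the vector labels in all 8 libraries. It lay between 0.148 and 0.213 FPKM in the 4 empty vector libraries and between 1621 and 5884 FPKM in the 4 CTBP2 libraries. The lowest CTBP2 library was 7617 times above the highest empty vector library. In both lines together the log2 fold change on the log2(FPKM + 1) scale was 11.25 (SE 0.39, limma adjusted p = 0.000136). The paralog CTBP1 (Entrez 1487) was at 40.7 to 64.1 FPKM over the 8 libraries, with a log2 fold change of 0.24 (SE 0.16, limma adjusted p = 0.444).

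Genes that mark the lines did not follow the line labels in 2 of the CTBP2 libraries. FGFR3 (Entrez 2261), a receptor tyrosine kinase activated by the t(4;14) translocation of NCI-H929, was at 13.8 and 21.7 FPKM in the NCI-H929 empty vector libraries and at 0.044 and 0.057 FPKM in those of MM.1S. It was at 22.2 FPKM in the library labelled MM.1S CTBP2 replicate 2 and at 0.040 FPKM in the library labelled NCI-H929 CTBP2 replicate 2. CCND2 (Entrez 894), a D-type cyclin, was at 94.6 and 115.4 FPKM in the MM.1S empty vector libraries and at 0.030 and 0.059 FPKM in those of NCI-H929. It was at 0.058 FPKM in the library labelled MM.1S CTBP2 replicate 2 and at 60.7 FPKM in the library labelled NCI-H929 CTBP2 replicate 2. MAF (Entrez 4094), WHSC1 (Entrez 7468), ITGB7 (Entrez 3695) and CCND1 (Entrez 595) were displaced the same way. The replicate 1 CTBP2 libraries of both lines lay with their own labels. Across genes, the library labelled NCI-H929 CTBP2 replicate 2 correlated with MM.1S CTBP2 replicate 1 at r = 0.985, and the library labelled MM.1S CTBP2 replicate 2 correlated with NCI-H929 CTBP2 replicate 1 at r = 0.962. Labels were kept as given in the main comparisons, and each count was repeated in the 6 remaining libraries, without both CTBP2 replicate 2 libraries, a choice made after seeing the data.

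**Figure D1:**
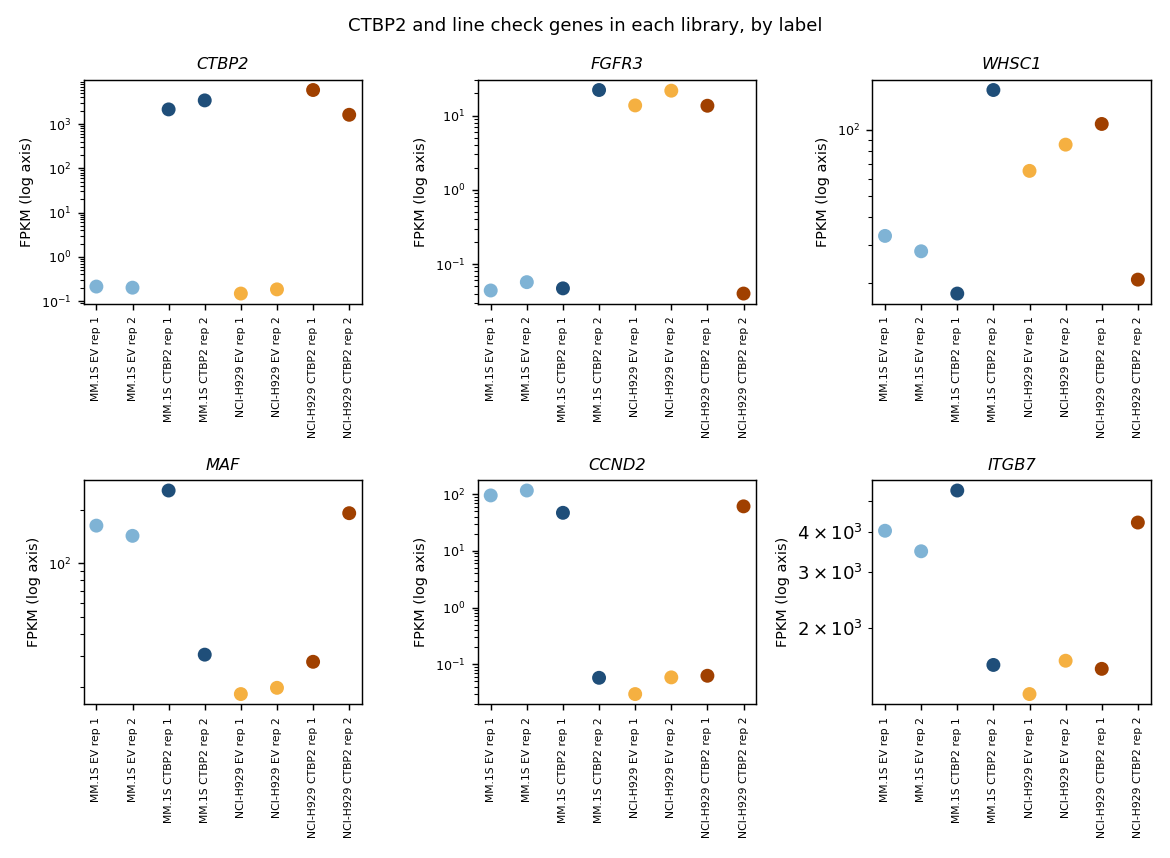
FPKM (log axes) of CTBP2 and 5 line check genes in each of the 8 libraries, 1 point per library, coloured by the labelled group (EV, empty vector; rep, replicate). CTBP2 is between 1621 and 5884 FPKM in the 4 CTBP2 libraries, while FGFR3 is at 22.2 FPKM in the library labelled MM.1S CTBP2 replicate 2 and at 0.040 FPKM in the library labelled NCI-H929 CTBP2 replicate 2.

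IRF4 (Entrez 3662), a transcription factor on which myeloma cells depend, fell with CTBP2 in both lines together. It was at 147.3 ± 12.5 FPKM in the empty vector libraries (SD, n = 4) and at 64.8 ± 4.31 FPKM in the CTBP2 libraries (SD, n = 4), with all 4 CTBP2 libraries below all 4 empty vector libraries. The log2 fold change was -1.17 (SE 0.13, limma adjusted p = 0.0309), and it was -1.21 (SE 0.15, limma adjusted p = 0.00559) without both CTBP2 replicate 2 libraries. With 1 library left out of all 8, IRF4 no longer passed in 6 of the 8 cases: its log2 fold change was then -1.12 to -1.23, with a limma adjusted p of 0.104 and 0.143 without MM.1S empty vector replicate 1 and 2, 0.154 and 0.0762 without NCI-H929 empty vector replicate 1 and 2, and 0.129 and 0.1 without the MM.1S and NCI-H929 CTBP2 replicate 1 library. The cases in which IRF4 still passed left out a library labelled CTBP2 replicate 2. Under the replicate block IRF4 did not pass (limma adjusted p = 0.147). It passed with the line labels of both CTBP2 replicate 2 libraries exchanged (limma adjusted p = 0.00166), a fit chosen after seeing the data. In the 6 remaining libraries its log2 fold change was -1.16 to -1.28 with 1 empty vector library also left out. MYC (Entrez 4609), which encodes a transcription factor that drives growth, did not pass with all 8 libraries, at a log2 fold change of -1.17 (SE 0.64, limma adjusted p = 0.328). It passed in the 6 remaining libraries, at -1.17 (SE 0.28, limma adjusted p = 0.0221), but not with MM.1S empty vector replicate 2 or NCI-H929 empty vector replicate 1 also left out (limma adjusted p = 0.0527 and 0.0534), with no filter (0.12) or under quantile normalization (0.0688). MYC was at 189.9 and 188.0 FPKM in the MM.1S empty vector libraries and at 133.9 FPKM in MM.1S CTBP2 replicate 1. It was at 114.6 and 92.9 FPKM in the NCI-H929 empty vector libraries and at 27.8 FPKM in NCI-H929 CTBP2 replicate 1. The library labelled MM.1S CTBP2 replicate 2 had 26.8 FPKM and the library labelled NCI-H929 CTBP2 replicate 2 had 138.7 FPKM. IKZF1, IKZF3, PRDM1 and XBP1, transcription factors of the plasma cell lineage, did not pass with all 8 libraries, at log2 fold changes of 0.34, 0.30, -0.33 and -0.19. The sign of XBP1 turned under quantile normalization, to 0.22, under equal totals without immunoglobulin genes and CTBP2, to 0.11, and without NCI-H929 empty vector replicate 2, to 0.039.

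**Figure D2:**
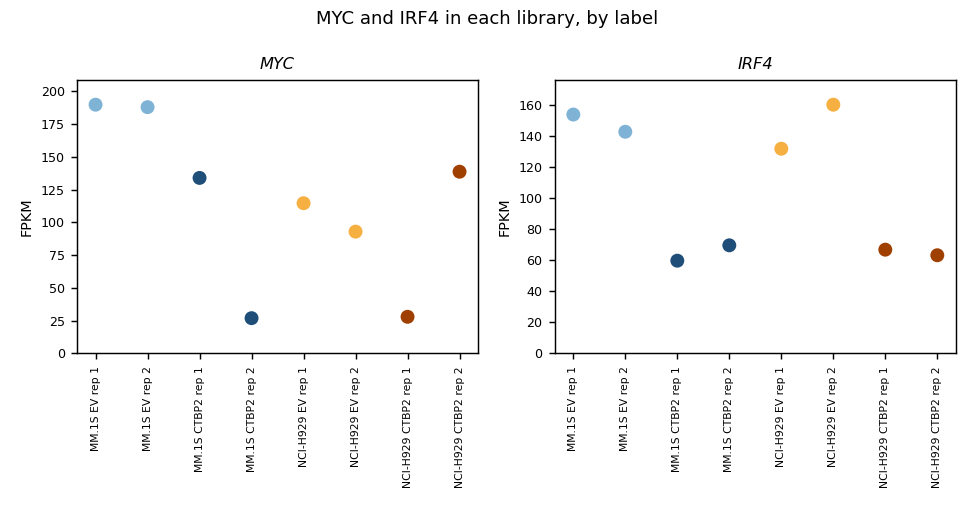
FPKM of MYC and IRF4 in each of the 8 libraries, 1 point per library, on axes that start at 0, coloured by the labelled group (EV, empty vector; rep, replicate). IRF4 is between 59.7 and 69.6 FPKM in the 4 CTBP2 libraries and between 131.9 and 160.3 FPKM in the 4 empty vector libraries.

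In both lines together, 420 of 12583 genes passed, 192 higher and 228 lower with CTBP2. CTBP2 itself, which the vector carries, is counted among those higher. Under equal totals without immunoglobulin genes and CTBP2 541 genes passed, 484 higher and 57 lower, so the balance of rises and falls depended on the scaling. Among the largest rises that met the naming rule were those of CEACAM1 (Entrez 634), a cell adhesion receptor, SEPP1 (Entrez 6414), a selenium transport protein, ALOX5AP (Entrez 241), which activates leukotriene synthesis, and PPIC (Entrez 5480), a cyclophilin. CEACAM1 rose from 0.465 ± 0.281 to 10.8 ± 7.84 FPKM (SD, n = 4), with a log2 fold change of 2.82 (SE 0.34). ALOX5AP rose from 4.91 ± 1.03 to 27.6 ± 4.54 FPKM (SD, n = 4), with a log2 fold change of 2.28 (SE 0.19). C4orf26, PIK3IP1, AMPD3 and YPEL3 rose by 2.10, 2.02, 1.92 and 1.90 on the log2 scale. The largest falls were in DSCC1 (Entrez 79075), a subunit of a clamp loader used in sister chromatid cohesion, NTHL1 (Entrez 4913), a DNA glycosylase, LYAR, TLCD1, CDC6 (Entrez 990), a replication licensing factor, MCM10, DEPTOR, an inhibitor of mTOR, GINS2, IFRD2 and BOLA3. DSCC1 fell from 12.4 ± 2.29 to 3.08 ± 1.35 FPKM (SD, n = 4), with a log2 fold change of -1.75 (SE 0.18). CDC6 fell from 32.0 ± 6.01 to 11.5 ± 4.35 FPKM (SD, n = 4), with a log2 fold change of -1.46 (SE 0.19). For each of these genes all 4 CTBP2 libraries lay beyond all 4 empty vector libraries. With the 6 remaining libraries alone 3082 genes passed, 1449 higher and 1633 lower (2570 higher and 770 lower under equal totals, and 519 and 344 with no filter, 863 in all), among them all 420, with the same sign, and 1321 to 2550 passed with 1 empty vector library also left out. These 6 libraries are among the same 8, so the overlap with the 420 is no independent support. With all 8 libraries and the replicate block, 1 gene passed instead of 420, and it was higher with CTBP2. CTBP2 itself is counted in all these numbers, so a count of 1 need not be a response of another gene. Nothing in the labels ties the replicate numbers to a shared day or culture. The count of 420, CTBP2 included, also depended on single libraries. It was 1 without MM.1S CTBP2 replicate 1, MM.1S empty vector replicate 1, NCI-H929 empty vector replicate 1 or NCI-H929 empty vector replicate 2. It was 2 without MM.1S empty vector replicate 2, 6 without NCI-H929 CTBP2 replicate 1, 198 without the library labelled MM.1S CTBP2 replicate 2 and 723 without the library labelled NCI-H929 CTBP2 replicate 2.

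Genes of growth and DNA replication were lower with CTBP2 in both lines together. Of 55 tested MYC target and ribosome biogenesis genes, 20 fell and 35 did not pass (45 fell when adjusted over the list alone), and the camera test gave an adjusted p of 1.62e-25 for the list, against 0.264 with an estimated correlation. SRM (Entrez 6723), spermidine synthase, fell from 296.8 ± 108 to 117.2 ± 32.0 FPKM (SD, n = 4). GNL3, NOP16 and MYBBP1A, nucleolar proteins, fell, with log2 fold changes of -1.1, -1.25 and -1.01. Of 39 G1/S cell cycle genes, 5 fell and 34 did not pass (28 fell when adjusted over the list alone), with a camera adjusted p of 2.39e-17, and 0.422 with an estimated correlation, and DSCC1, CDC6, TIPIN and GINS2 led them. Of 41 G2/M cell cycle genes, 2 fell, UBE2C and NUF2, with log2 fold changes of -1.1 and -1.05 (21 when adjusted over the list alone), with a camera adjusted p of 9.59e-14, and 0.464 with an estimated correlation. Of the same lists, 51, 36 and 22 members fell in the 6 remaining libraries. By line, 30, 35 and 27 members fell there in MM.1S, and 34, 12 and 0 in NCI-H929. These counts by line are fragile, since with 1 empty vector library left out only 0 to 18 genes in all passed in MM.1S and 3 to 80 in NCI-H929. The difference between lines passed by camera for the G1/S and G2/M lists (adjusted p = 1.18e-10 and 4.86e-10) but not with an estimated correlation (adjusted p = 0.875 for both), and no member of either list passed for it.

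Stress, amino acid and translation lists were also lower. AHSA1, a co-chaperone of HSP90, fell by 0.96 on the log2 scale and was the called member of the 17 heat shock genes (camera adjusted p = 6.43e-06, and 0.422 with an estimated correlation; 6 when adjusted over the list alone). Of 32 ATF4 amino acid response genes 4 fell, PSAT1, XPOT, GARS and MTHFD2, with log2 fold changes of -1.24, -0.84, -0.99 and -0.77 (camera adjusted p = 1.68e-05, and 0.422 with an estimated correlation; 11 lower and 1 higher when adjusted over the list alone). PDIA4, a disulfide isomerase of the endoplasmic reticulum, fell by 0.70 on the log2 scale among 31 unfolded protein response genes (camera adjusted p = 0.00205, and 0.422 with an estimated correlation; 2 when adjusted over the list alone). No member passed among 75 cytoplasmic ribosomal protein genes (mean log2 fold change -0.50, camera adjusted p = 1.38e-10), 53 nuclear oxidative phosphorylation genes (-0.26, camera adjusted p = 6.28e-05) or 28 cholesterol and fatty acid synthesis genes (-0.35, camera adjusted p = 0.00516). With an estimated correlation the adjusted p was 0.464 for each of these 3 lists. Without both CTBP2 replicate 2 libraries 10 heat shock, 16 ATF4 and 8 unfolded protein response genes fell, with 1, 3 and 2 ribosomal, oxidative phosphorylation and cholesterol genes, and 2 ATF4 genes rose. The direction of the oxidative phosphorylation list is uncertain, since its mean turned to 0.026 under quantile normalization and to 0.038 under equal totals without immunoglobulin genes and CTBP2, a scaling that moved the median of all genes from 0.035 to 0.267. Equal totals also turned the mean of the ribosomal protein list in the 6 remaining libraries, to 0.031.

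Interferon-stimulated genes were higher with CTBP2. Of 40 tested members 5 rose and none fell (11 when adjusted over the list alone), with a camera adjusted p of 6.43e-07 and an adjusted p of 0.262 with an estimated correlation. Without both CTBP2 replicate 2 libraries 18 rose and 1 fell (camera adjusted p = 1.25e-08, and 0.401 with an estimated correlation). MX1 (Entrez 4599), an antiviral GTPase, rose from 4.73 ± 0.885 to 14.3 ± 2.65 FPKM (SD, n = 4). XAF1, PARP14 and PARP9 rose by 1.38, 1.69 and 1.56 on the log2 scale. Replication-dependent histone genes had a mean log2 fold change of 1.37 over 23 members, none of which passed (camera adjusted p = 5e-05, and 0.464 with an estimated correlation). HIST1H4E had a log2 fold change of 1.74 (SE 0.55) and HIST1H2BF 1.90 (SE 0.60). In the 6 remaining libraries 15 of the 23 rose and none fell, at a mean log2 fold change of 1.34 (camera adjusted p = 1.25e-08, and 0.401 with an estimated correlation). By line, 7 rose in MM.1S and 18 in NCI-H929 there, and these counts are fragile in the same way. CGN, a tight junction protein, rose by 0.84 on the log2 scale among 13 epithelial genes (camera adjusted p = 0.0381, and 0.49 with an estimated correlation; 2 when adjusted over the list alone). CFLAR, an inhibitor of caspase 8 activation, rose by 0.84 on the log2 scale among 22 NF-kB target genes (camera adjusted p = 0.0381, and 0.422 with an estimated correlation; 1 when adjusted over the list alone). Of the epithelial and NF-kB lists 6 and 8 members rose in the 6 remaining libraries and none fell.

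Of the 26 lists 13 passed by camera, 4 higher and 9 lower, and none passed with an estimated correlation. The latter test had little power at 5 residual degrees of freedom, so not passing it cannot decide against a list. In NCI-H929 as labelled, the interferon list had an estimated correlation of -0.012, below the preset 0.01. Its camera adjusted p still went from 5.63e-08 to 0.062. By fry 4 of the 26 passed in both lines together: the MYC target and interferon lists (fry adjusted p = 0.00708 each), heat shock genes (0.0379) and G1/S genes (0.0456). The other lists called by camera did not pass by fry. Among lists that did not pass, SPI1 and BCL6, transcription factors of the B cell lineage, rose by 0.91 and 0.80 on the log2 scale within the B cell and MHC class II list (camera adjusted p = 0.0797), whose mean of 0.371 turned to -0.088 without the library labelled NCI-H929 CTBP2 replicate 2. That fit kept the other library with displaced line genes, and without both the mean was 0.421. BBC3 and BMF, proapoptotic BH3-only proteins, rose by 1.01 and 1.83 on the log2 scale within the apoptosis regulators (camera adjusted p = 0.4). BBC3 and TP53I3, the latter by 0.81, rose within the p53 target list (camera adjusted p = 0.0761), and BHLHE40 by 1.58 within the glycolysis and hypoxia list (camera adjusted p = 0.285), whose mean of -0.082 turned to 0.047 under quantile normalization and to 0.181 under equal totals. The plasma cell and myeloma identity list had IRF4 as its only called member of 26 with all 8 libraries (camera adjusted p = 0.0761), and its mean of -0.241 turned to 0.03 under equal totals. With all 8 libraries none passed among 21 CTBP corepressor partners (camera adjusted p = 0.446), 18 immediate early genes (0.288), 23 adhesion and homing genes (0.446) and 17 NRF2 antioxidant genes (0.823); EHMT2, a histone methyltransferase, had a log2 fold change of -0.49, BTG2 0.90, ITGA6 0.98 and HMOX1 0.82. Of the lists, 17 passed by camera in the 6 remaining libraries, 7 higher and 10 lower, and none with an estimated correlation. By fry 5 passed there: MYC target and interferon genes (fry adjusted p = 0.0318 each), heat shock and epithelial genes (0.0294 each) and unfolded protein response genes (0.0124). G1/S genes no longer passed by fry (0.0559). Among the 17 called by camera were the B cell list (4 higher, camera adjusted p = 0.00914, and 0.446 with an estimated correlation), the plasma cell list (3 higher and 7 lower, camera adjusted p = 0.0157, and 0.401) and the immediate early genes (4 higher and 1 lower, camera adjusted p = 0.029, and 0.602). RBBP8 and EHMT2 fell there, with log2 fold changes of -0.83 and -0.61, and EP300 and KLF3 rose by 0.68 and 0.48 among the CTBP partners, whose list did not pass (camera adjusted p = 0.607). Nor did the adhesion list pass there, with 4 members higher (camera adjusted p = 0.433), or the NRF2 list, with 1 higher and 2 lower (0.478). The p53 list with 7 higher and 1 lower (camera adjusted p = 0.104), the apoptosis list with 8 and 3 (0.235) and the glycolysis list with 3 and 8 (0.0994) did not pass either.

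**Figure D3:**
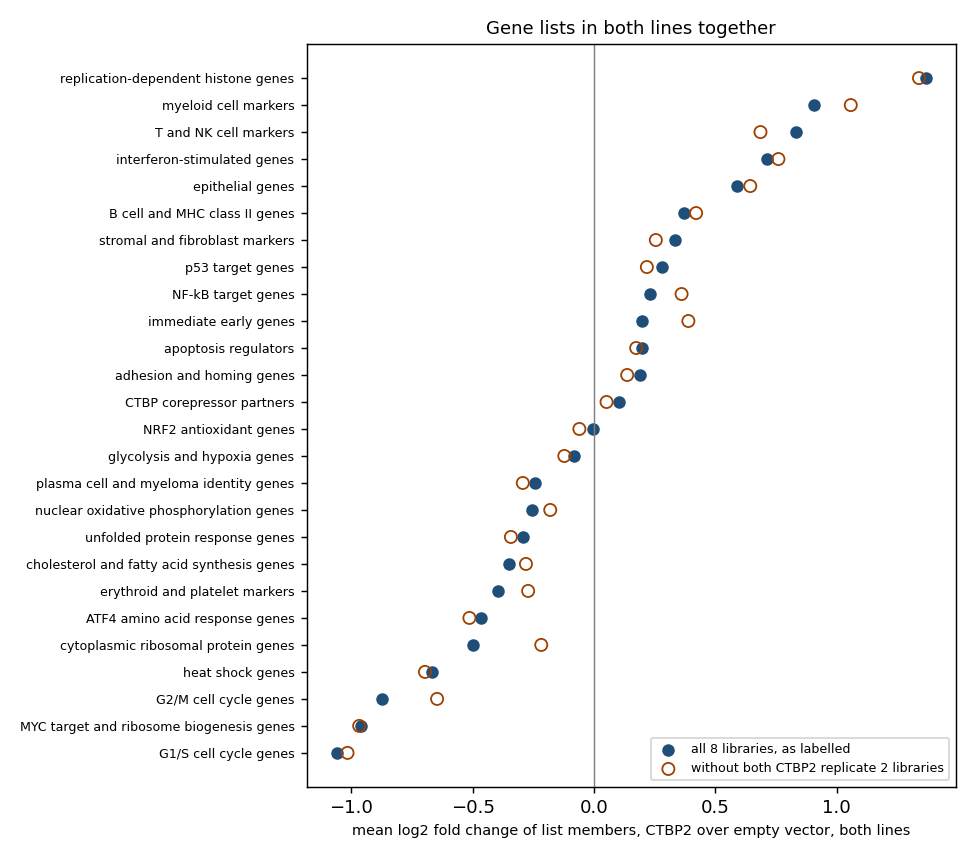
Mean log2 fold change of the tested members of each of the 26 gene lists, CTBP2 over empty vector in both lines together, on the log2(FPKM + 1) scale, with filled points for all 8 libraries as labelled and open points without both CTBP2 replicate 2 libraries. The G1/S list lies at -1.06 and the interferon list at 0.711 with all 8 libraries, and at -1.02 and 0.76 without those libraries.

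Of the markers of other cell types, 3 myeloid markers were tested and had a mean log2 fold change of 0.907 with none called (camera adjusted p = 0.0761), with ITGAM at 0.112 FPKM in the empty vector and 1.86 FPKM in the CTBP2 libraries on average and CD68 at 11.5 to 44.5 FPKM over all 8. With the 6 remaining libraries CD68 and S100A9 rose, by 0.97 and 1.06 on the log2 scale, and the myeloid list passed (camera adjusted p = 0.0223, and 0.401 with an estimated correlation). By line its camera adjusted p was 0.000946 in MM.1S there, and 0.541 with an estimated correlation, and it did not pass in NCI-H929 (camera adjusted p = 0.138). Among 4 tested T and NK cell markers (camera adjusted p = 0.288) CD3E averaged 1.90 FPKM in the empty vector and 19.2 FPKM in the CTBP2 libraries and did not pass (limma adjusted p = 0.207). It was at 53.1 FPKM in the library labelled MM.1S CTBP2 replicate 2, 16.7 FPKM in NCI-H929 CTBP2 replicate 1 and at most 4.76 FPKM in the other libraries, and it rose by 1.91 on the log2 scale in the 6 remaining ones (limma adjusted p = 0.00573). The T and NK list did not pass there in both lines together (camera adjusted p = 0.104) or in MM.1S (0.371). In NCI-H929 it passed, with 2 of 4 members higher (camera adjusted p = 0.0485, and 0.578 with an estimated correlation). The erythroid and platelet and the stromal lists had 3 and 4 tested members, none called, with camera adjusted p of 0.296 and 0.446. ACTA2, of the stromal list, rose by 1.37 in the 6 remaining libraries, where neither list passed (camera adjusted p = 0.421 and 0.645). The number of genes at 1 FPKM or more was 10615 to 11012 in the empty vector libraries and 11351 to 11912 in the CTBP2 libraries.

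Within MM.1S as labelled, 3 genes passed, 1 higher and 2 lower (1 higher and 1 lower under each of the other scalings), 2429 had an unadjusted p under 0.05, and 0 to 7 passed with 1 of the 8 libraries left out. The 1 gene higher as labelled was CTBP2 itself. The call that met the naming rule was HBD (Entrez 3045), delta globin, with a log2 fold change of -2.64 (SE 0.21, limma adjusted p = 0.0495). HBD was at 35.1 and 34.0 FPKM in the MM.1S empty vector libraries, 5.25 FPKM in MM.1S CTBP2 replicate 1 and 4.25 FPKM in the library labelled MM.1S CTBP2 replicate 2, where the NCI-H929 empty vector libraries had 4.65 and 3.41 FPKM. As labelled its call ended with a pseudocount of 0.1, with no filter, under each of the other scalings, without the variance trend and with any 1 library left out. In the 6 remaining libraries, where MM.1S CTBP2 replicate 1 stands alone and is assumed to vary like the other groups, 1429 genes passed, 730 higher and 699 lower (1211 higher and 472 lower under equal totals, and 465 and 65 with no filter). UBD (Entrez 10537), an interferon- and TNF-inducible ubiquitin-like protein, was at 0.821 and 0.361 FPKM in the empty vector libraries and at 48.6 FPKM in MM.1S CTBP2 replicate 1. MILR1, CHRNA1, LY86, KRT15 and CEACAM1 followed with log2 fold changes of 2.81, 2.77, 2.71, 2.70 and 2.67. The largest fall was in GPRC5D (Entrez 55507), an orphan receptor on plasma cells, at 104.9 and 69.8 FPKM with the empty vector and 6.20 FPKM in MM.1S CTBP2 replicate 1. HRASLS2, HBD, CYP26A1 and DSCC1 followed with log2 fold changes of -2.91, -2.51, -2.23 and -1.97. NUDT4P1, at -2.77, also met the rule but is uncertain, since it has near-identical copies in the genome and was at 0.016 and 4.94 FPKM in the libraries labelled MM.1S CTBP2. IRF4 fell by 1.30 (limma adjusted p = 0.0212), and MYC, with a log2 fold change of -0.49, did not pass (limma adjusted p = 0.166). The count and the IRF4 call rested on every empty vector library: 9 genes passed without MM.1S empty vector replicate 1 and 0 without MM.1S empty vector replicate 2, and 18 passed without either of the NCI-H929 empty vector libraries, with IRF4 at a limma adjusted p of 0.147, 0.206, 0.0972 and 0.0977 in that order. IRF4 did not pass with no filter either (limma adjusted p = 0.0833).

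Within NCI-H929 as labelled, 7 genes passed, 6 higher and 1 lower, 2090 had an unadjusted p under 0.05, and 1 to 4 passed with 1 of the 8 libraries left out. CTBP2 itself is 1 of the 6 higher as labelled, and the other 5 are not the vector's gene. CASP1, CARD16, PPIC and F11R met the naming rule, with log2 fold changes of 3.66, 2.92, 2.80 and 2.63. CASP1 was 0.935 to 1.1 FPKM in the NCI-H929 empty vector libraries, 18.8 FPKM in NCI-H929 CTBP2 replicate 1 and 20.9 to 24.1 FPKM in the MM.1S empty vector libraries, and it was at 31.5 FPKM in the library labelled NCI-H929 CTBP2 replicate 2. In the 6 remaining libraries 1929 genes passed, 1109 higher and 820 lower (1852 higher and 363 lower under equal totals, and 1296 and 254 with no filter). IFIT3 (Entrez 3437), an interferon-induced protein, was at 0.403 and 0.408 FPKM in the empty vector libraries and at 26.2 FPKM in NCI-H929 CTBP2 replicate 1. CD1A, FCGR2B, CASP1 and RTP4 had log2 fold changes of 3.57, 3.33, 3.30 and 3.18. MYC was among the 10 largest falls, at -1.85 (SE 0.21, limma adjusted p = 0.00725), with PRR22, DDN, CTXN1, PDGFB and FAM189B at -2.31, -1.96, -1.91, -1.88 and -1.87. RPL21 and NUDT4P1 also met the rule but are uncertain, since both have near-identical copies in the genome and their values switched within groups: RPL21 was at 14.6 and 0.015 FPKM in the MM.1S empty vector libraries, and NUDT4P1 at 0.001 and 4.11 FPKM in the libraries labelled NCI-H929 CTBP2. IRF4 fell by 1.11 (limma adjusted p = 0.0214), but did not pass with no filter (0.0664) or under quantile normalization (0.063). With 1 empty vector library left out the count was 3 for either of MM.1S, 13 for NCI-H929 replicate 1 and 80 for NCI-H929 replicate 2, and neither MYC (limma adjusted p = 0.0546 to 0.103) nor IRF4 (0.0957 to 0.112) passed in any of these cases.

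The responses of both lines were compared across 12582 genes other than CTBP2. As labelled, the log2 fold changes had r = -0.068 and rho = 0.050, and no gene was called in the same direction in both. They had r = 0.543 and rho = 0.630 in the 6 remaining libraries, across genes, which are not independent replicates. There, 320 genes rose in both lines and 244 fell in both, while 8 called in both moved in opposite directions. The fold changes of the lines share no library, but their calls share the residual variance of the 4 empty vector libraries, so a gene with a small variance can be called in both without a shared response, and the size of the overlap is no measure of one. A difference between lines passed for 2 genes as labelled, MIR142 and SNORA68 (0 higher and 1 lower under equal totals), 0 to 3 passed with 1 library left out, and 912 genes had an unadjusted p under 0.05. Both are short transcripts, named here because the count was small and chosen after their values were seen. In the 6 remaining libraries 44 genes passed, 31 with a log2 fold change higher in NCI-H929 and 13 the other way, and 0 to 14 passed with 1 empty vector library also left out. The count was 16 with a pseudocount of 0.1, 141 under equal totals and 649 with no filter, 453 higher and 196 lower. The difference for MYC was 0.92 (limma adjusted p = 0.698) as labelled and -1.36 (SE 0.30, limma adjusted p = 0.143) in these 6, and passed in neither. It passed at -1.41 (limma adjusted p = 0.0362) with the line labels of both CTBP2 replicate 2 libraries exchanged, a fit chosen after seeing the data. Whether the difference passed thus depended on how these libraries were used. As labelled, each line's CTBP2 mean includes a library with the other line's expression, so 0.92 cannot give the direction. MYC was at 27.8 and 26.8 FPKM in the CTBP2 libraries with NCI-H929 expression, against 114.6 and 92.9 with the empty vector. In the CTBP2 libraries with MM.1S expression it was at 133.9 and 138.7 FPKM, against 189.9 and 188.0.

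The lines differed at baseline, between empty vector libraries. As labelled 5 genes passed, 1 higher and 4 lower in NCI-H929 (1 and 1 under quantile normalization) and 0 to 5 with 1 library left out, with 3064 at an unadjusted p under 0.05. CASP1, HBD and F11R, all lower in NCI-H929, met the naming rule. In the 6 remaining libraries, with the empty vector libraries alone giving the spread, 6860 genes passed, 2978 higher and 3882 lower in NCI-H929 (2305 higher and 4843 lower under equal totals), and 3916 to 4649 with 1 empty vector library left out. S100A4, a calcium-binding protein, was at 0.263 ± 0.372 FPKM in MM.1S and 1696 ± 143 FPKM in NCI-H929 (SD, n = 2). NES, PAGE5, IL32 and CTAG1B were higher in NCI-H929 by 8.51, 8.01, 7.78 and 7.71 on the log2 scale. CD74, the MHC class II invariant chain, was at 816.6 ± 129 FPKM in MM.1S and 0.251 ± 0.0182 FPKM in NCI-H929 (SD, n = 2). LAPTM5, PCP4, QPCT and CD9 had log2 differences of -9.10, -8.11, -7.42 and -7.34.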

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

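The tests of an exchange, of a mixture and of a switching response in the displaced libraries, the fits without them or with exchanged labels, and the test of the amount of virus were chosen after the result was seen. The tests of scaling, trend, splits and myeloid cells were written before their values were seen, for patterns noticed among the leading genes.

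The response differed between lines, by the interaction term, for MIR142 by -11.07 and for SNORA68 by 4.14 on the log2 scale with all 8 libraries. MIR142 was listed at 3364 and 1368 FPKM in the NCI-H929 empty vector libraries and at 0 in the other 6, and SNORA68 at 16.0 and 17.4 FPKM in the MM.1S empty vector libraries and at 0 in the other 6. No gene differed in response with MM.1S CTBP2 replicate 1, MM.1S empty vector replicate 2 or the library labelled MM.1S CTBP2 replicate 2 left out alone. The calls did not rest on the last of these, since both genes were still called without both CTBP2 replicate 2 libraries. Their differences there were unchanged, at -11.07 and 4.14. Without both CTBP2 replicate 2 libraries the largest differences that met the naming rule and are reported here were 3.41 for GPRC5D, 3.38 for HBD, 3.05 for CD1A, 2.92 for OASL and 2.82 for CASP1. In the other direction they were -4.41 for UBD, -2.06 for SPTLC3, -1.93 for ITGAM and -1.87 for C10orf128. Each of these rests on 1 CTBP2 library per line. With all 8 libraries none of these genes passed. The library labelled MM.1S CTBP2 replicate 2, with NCI-H929 expression, differed from NCI-H929 CTBP2 replicate 1 for some of them. GPRC5D was at 12.3 FPKM against 36.3, below the 39.7 and 42.8 FPKM of the NCI-H929 empty vector libraries. OASL was at 2.42 FPKM against 16.2, and HBD at 4.25 against 8.10. CD1A, at 7.08 against 13.3, and CASP1, at 21.5 against 18.8, were raised in both.

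The libraries labelled CTBP2 replicate 2 carried the expression of the other line, and a candidate explanation is an exchange of labels or columns between them. The bound set for it, over 0.9 of the genes called between the lines' empty vector libraries nearer to the other line in both libraries, was missed: over 6860 genes the share was 0.9 in the library labelled NCI-H929 CTBP2 replicate 2 and 0.691 in the library labelled MM.1S CTBP2 replicate 2. The bound had not fixed how large a difference to ask for, and with a minimum log2 difference of 1 or 2 the share was 0.958 and 0.979 in the NCI-H929-labelled library but 0.768 and 0.882 in the MM.1S-labelled library, so it was missed under all 3 definitions; in the replicate 1 CTBP2 libraries the highest shares were 0.222, 0.142 and 0.065, and the bound against a response to CTBP2, at most 0.1, was met with a minimum of 2 but not with the wider definitions. At genes of 10 FPKM or more in 1 line and at most 0.1 in the other, the other line's genes had medians of at least 20.25 FPKM in both libraries and the labelled line's own at most 0.1442 FPKM, which argues against a mixture of lines, and the own genes kept medians of at least 20.02 FPKM in the replicate 1 CTBP2 libraries, which argues against a response that switches them. The replicate 1 CTBP2 libraries, which lay with their own labels, had shares of 0.151 in MM.1S and 0.222 in NCI-H929 over the 6860 genes. A CTBP2 library of the other line could therefore miss the bound there, so missing it over all line genes cannot decide against an exchange. With a minimum log2 difference of 2 the bound was within reach, and the MM.1S-labelled library missed it at 0.882. Each displaced library correlated most with the other line's CTBP2 replicate 1, at r = 0.985 and 0.962. An exchange thus has the values it needs at the on-off genes, and no record in the labels settles it.

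With both line labels exchanged the both-lines fold changes are identical by construction, and the count of genes was 4287 against 420. Of the 34 splits of the 8 libraries into 4 and 4 that could be fitted beside the line, 2 gave at least 420 genes, the real one included. The other is the split that follows the lines' expression, with 4842 genes, a structure of the samples, and the next highest gave 1. Every split was fitted beside the labelled line, which the CTBP2 replicate 2 libraries did not follow, so line differences stayed in the spread. Chance can thus be neither excluded nor favoured by this count.

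The MYC target and G1/S lists were lower with CTBP2 by camera, but did not pass with an estimated correlation (camera adjusted p = 0.264 and 0.422), a test with little power here. Median-of-ratios and quantile rescaling do not account for it: under them the list mean nearest to 0 was -0.799. Equal totals, which moved the median of all genes from 0.035 to 0.267, were not part of this test. The FPKM totals were 459733 to 544210 in the CTBP2 and 547097 to 659837 in the empty vector libraries, so scaling is set aside only for the rescalings tested. A smooth trend with expression, transcript length and GC content took up 16.7% of the variance of the fold changes, and the list mean nearest to 0 after its removal was -0.75, from -0.958 before. A biological response to CTBP2 is a hypothesis that stays open.

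Interferon-stimulated genes had a mean log2 fold change of 0.711, and whether it follows the amount of virus cannot be told apart from the vector, since the labels give no titre. For the myeloid-type genes, myeloid cells in the cultures may be set aside as the source: of the transcripts abundant in such cells, LYZ was at most 0.552 FPKM and S100A8 0 in all 4 CTBP2 libraries, with S100A9 at up to 4.52 FPKM. The source of the rise in CD68 and S100A9 without both CTBP2 replicate 2 libraries stays open.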

How the results depend on the processing

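The fits without both CTBP2 replicate 2 libraries and with exchanged line labels were chosen after seeing the data. Counts of changed genes include CTBP2 itself wherever it passed. Of 4678 values of named genes and lists under alternatives, 66 lay on the other side of 0; the cause was not tested except where fewer libraries were fitted. Values in parentheses after "remaining" are for the 6 libraries left without both CTBP2 replicate 2 libraries.

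With a pseudocount of 0.1, 1 gene changed in MM.1S and 1 differed in response, the correlation of responses was -0.171 and the NRF2 list mean 0.023 (remaining: 762 genes in MM.1S, 16 differing in response, correlation 0.514). With no filter on low values, 3 genes changed in NCI-H929, 2 differed at baseline and the correlation was -0.059 (remaining: 530 genes in MM.1S, 863 in both lines together, 649 differing in response, correlation 0.486). With at least 5 FPKM in 2 libraries, 1 gene differed in response and the correlation was -0.104 (remaining: 19 genes and 0.546). Without the variance trend 3 genes differed at baseline (remaining: 19 differing in response). With a log2 fold change of at least 1, 225 genes changed in both lines together (remaining: 810 in MM.1S, 951 in NCI-H929, 645 in both lines together and 3070 at baseline).

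Under median-of-ratios scaling the correlation was -0.063, CTBP1 in MM.1S 0.063, the difference of IRF4 between lines -0.076, IRF4 at baseline 0.1, PRDM1 at baseline 0.105 and the NRF2 list 0.021. Quantile normalization gave 2 genes at baseline, a correlation of -0.104, XBP1 in both lines together 0.222, CTBP1 in MM.1S 0.278, PRDM1 in MM.1S 0.063, the difference of CTBP2 between lines -0.06, the glycolysis list 0.047, the oxidative phosphorylation list 0.026 and the NRF2 list 0.076 (remaining: correlation 0.487, oxidative phosphorylation 0.078, NRF2 0.017). Equal totals without immunoglobulin genes and CTBP2 gave 1 gene differing in response, a correlation of -0.086, XBP1 in both lines together 0.11, CTBP1 in MM.1S 0.241, PRDM1 in MM.1S 0.055, the plasma cell list 0.03, the glycolysis list 0.181, the oxidative phosphorylation list 0.038 and the NRF2 list 0.259 (remaining: 141 genes differing in response, correlation 0.515, IKZF3 in NCI-H929 0.015, glycolysis 0.098, oxidative phosphorylation 0.068, ribosomal proteins 0.031, NRF2 0.159).

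Without both CTBP2 replicate 2 libraries 1429 genes changed in MM.1S, 1929 in NCI-H929 and 3082 in both lines together, 44 differed in response and 6860 at baseline. The correlation was 0.543, CTBP1 in MM.1S 0.098, XBP1 in MM.1S -0.386, IKZF3 in NCI-H929 -0.255, and the difference between lines -1.359 for MYC and 0.313 for IKZF1. With exchanged labels the counts were 688, 4138, 4287, 158 and 6395, the correlation 0.628, CTBP1 in MM.1S 0.132, XBP1 in MM.1S -0.314, and the difference between lines -1.411 for MYC, which passed (limma adjusted p = 0.0362), 0.616 for IKZF1, 0.269 for PRDM1 and 0.253 for XBP1. With the libraries of NCI-H929 alone 1 gene changed there, and averaging the effects of both lines gave 252 genes. Of the gene lists in both lines together 0 passed with an estimated correlation in either set of libraries. By fry 4 passed with all 8 libraries and 5 without both CTBP2 replicate 2 libraries.

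With the replicate block 0 genes changed in MM.1S, 0 in NCI-H929 and 1 in both lines together, and 0 differed in response. The labels tie the numbers to no shared day or culture. The deviations of same-numbered libraries had r = 0.012 in MM.1S and 0.109 in NCI-H929. As labelled, both CTBP2 replicate 2 libraries carried the other line's expression, so these low values cannot tell whether the numbers are paired.

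With 1 library left out at a time, 0 to 7 genes changed in MM.1S, 1 to 4 in NCI-H929 and 1 to 723 in both lines together, 0 to 3 differed in response and 0 to 5 at baseline, and the correlation was -0.322 to 0.488. The log2 fold changes ranged from -0.141 to 0.098 for CTBP1, -0.446 to 0.032 for PRDM1 and -0.386 to 0.824 for XBP1 in MM.1S, -1.853 to 0.423 for MYC and -0.255 to 0.417 for IKZF3 in NCI-H929, and -0.511 to 0.039 for XBP1 in both lines together. Differences between lines ranged from -0.693 to 1.167 for CTBP2, -0.222 to 2.058 for MYC, -0.1 to 0.179 for IRF4 and -0.44 to 0.206 for IKZF1. Baseline values ranged from -0.168 to 0.112 for IRF4 and -0.129 to 0.087 for PRDM1, and list means from -0.088 to 0.87 for B cell genes and -0.075 to 0.093 for NRF2 genes. Among the remaining libraries 0 to 18 genes changed in MM.1S, 3 to 80 in NCI-H929 and 1321 to 2550 in both lines together, 0 to 14 differed in response and 3916 to 4649 at baseline, the correlation was 0.46 to 0.564, IKZF1 in MM.1S -0.049 to 0.203 and the NRF2 list -0.135 to 0.025. A group left with 1 library was assumed to vary like the others.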
